A study of Mus musculus with 6 samples.

How the data were processed

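RNA sequencing was done on 2 sorted populations of naive kidney from C57BL/6 wild-type mice. Type 1 innate lymphoid cells (ILC1) are tissue lymphocytes related to natural killer cells and were gated as CD49a-positive, CD49b low to intermediate, NK1.1+NKp46+CD3- cells. Conventional natural killer cells (cNK), the circulating cytotoxic innate lymphocytes, were gated as CD49b high NK1.1+NKp46+CD3- cells. Per the labels' protocols, kidneys were digested, leukocytes were enriched on Percoll and with CD45 beads after lysis of erythrocytes, and total RNA was taken from the sorted cells. The labels name 3 pools per population, numbered 1 to 3. They do not say how many mice went into a pool, or whether pools came from separate animals, so p-values measure the spread between these pools. Whether pools of the same number in both populations came from the same mice is not stated either, and the main test took them as unpaired.

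The authors deposited raw counts of reads per gene for the 6 libraries, 2 columns with the mean count of each population, and 2 ranked lists of gene symbols. The submitters' processing notes name Trimmomatic 0.38, STAR 2.6.1, R 4.03, DESeq and DESeq2 1.30.0 with the genome build GRCm38. The counting program, the annotation release, the treatment of reads that match several genes and the use of strand are not given in the sources used here. Reads of genes with near-identical copies, such as the Ly49 (Klra) family, and of overlapping or antisense genes are therefore uncertain. The deposited values were whole numbers, were not normalized, and every gene had at least 5 counts over the 6 libraries. The mean columns that the authors deposited are an averaged signal, and each equalled the mean of the 3 count columns of its population. A trailing entry with no gene identifier and no counts per library was left out. Of 23841 gene identifiers, 23798 matched the GENCODE M21 annotation, which gave gene positions on GRCm38, and 424 had no symbol in the table. Those without a symbol held between 0.413% and 0.836% of the counts of a library.

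Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter by group, a robust quasi-likelihood fit on population alone and Benjamini-Hochberg adjustment at 0.05. The filter kept 16144 genes. Fold changes are log2 of ILC1 over cNK with the standard error (SE) taken from the quasi-likelihood F statistic, and levels are TMM-scaled CPM (counts scaled to a common library size) computed from the deposited counts, given as mean ± SD of 3 libraries. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over 33 lists with at least 4 tested members. Named genes were the genes of the sort gate, the 10 largest changes per direction among genes past the threshold, at a mean of at least 10 CPM and with no overlap between the populations, up to 4 passing members of each list per direction (3 of the highest level where fewer than 2 passed), and 22 genes set in advance. Gene models without a proper symbol were left out of the largest changes, and some genes that the rule names are not reported here. The lists, this rule, the design and the alternative settings were set before the data were examined. A further 5 lists, the symbol families and 4 alternatives were chosen after seeing the data.

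The libraries held between 22633440 and 28327265 counts, so that 1 count was worth between 0.0353 and 0.0442 CPM. No pair of libraries was identical. The test was tried on simulated data drawn from the means, library sizes and dispersions of this comparison, with 200 changed genes among 15734 genes. It recovered 4 of 50 genes changed 2-fold, 32 of 50 changed 4-fold, 38 of 50 changed 8-fold and 46 of 50 changed 16-fold, and 10 of its 130 calls were of unchanged genes. A change of 2-fold was thus mostly missed in the simulation. With 130 calls there against 930 in the data, the adjusted threshold was stricter in the simulation. Its genes were also drawn independently, so its recovery need not hold for the data. Alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter and a stricter filter, a block for the pool number, stricter thresholds, and leaving out each library. The alternatives added later left out mitochondrial genes with their nuclear copies, used the mitochondrial or the kidney epithelial share as a covariate, or left out both ILC1 pool 3 and cNK pool 2.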

Results

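Gene expression was measured by RNA sequencing in ILC1 and cNK cells sorted from naive mouse kidney, with 3 pools of each population. The ILC1 libraries held 22633440, 28327265 and 25081487 counts and the cNK libraries 27438848, 26315110 and 24899746. The study as a whole asked about both populations in experimental glomerulonephritis, and the libraries described here compare them in the kidney without disease.

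The genes of the sort gate were examined first. Itga1, which encodes CD49a, was higher in ILC1, at 137 ± 41.7 CPM (mean ± SD, n = 3) against 11.2 ± 3.56 CPM in cNK, a log2 fold change of 3.62 ± 0.35 (SE). Itga2, which encodes CD49b, was higher in cNK, at 107 ± 45.8 against 16.6 ± 7.30 CPM (log2 fold change -2.69 ± 0.43). Both genes lie side by side on GRCm38 (chromosome 13, 114953096 to 115101964 for Itga1 and chromosome 13, 114833081 to 114932100 for Itga2). Klrb1c (NK1.1), Ncr1 (NKp46) and Ptprc (CD45), used for both gates, did not pass the edgeR test, with log2 fold changes of -0.34, 0.19 and -0.50. Of the CD3 genes, by which T cells were gated out, Cd3e stood at 2.65 ± 1.55 CPM in ILC1 and 1.24 ± 1.07 CPM in cNK and Cd3d at 6.39 ± 2.73 and 10.5 ± 3.31 CPM, without a call, whereas Cd3g was higher in ILC1 (59.4 ± 13.2 against 10.6 ± 2.57 CPM). The edgeR adjusted p was 0.00251 for Itga1, 0.0140 for Itga2 and 0.00384 for Cd3g, and that of Itga2 was 0.0753 without ILC1 pool 2 and 0.0539 without cNK pool 3. Ptprc was called lower in ILC1 with the mitochondrial share as covariate (log2 fold change -0.96, adjusted p = 0.0173). Of the 8 gate genes, 2 were higher in ILC1 and 1 in cNK, with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.223, toward ILC1 while its median log2 fold change was -0.08). Fry called the list higher in ILC1 (adjusted p = 0.0199).

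Across the transcriptome, 657 genes were higher in ILC1 and 273 were higher in cNK, of 16144 tested. The largest differences toward ILC1 were in Ccl1, a chemokine and ligand of Ccr8 (log2 fold change 7.26 ± 0.97), Mmp9, a matrix metalloproteinase (6.71 ± 0.40), the chemokine receptor Cxcr6 (6.58 ± 0.27), Pdcd1, which encodes the inhibitory receptor PD-1 (6.58 ± 0.27), Ccr8 (6.01 ± 0.26) and Zfp683, which encodes the transcription factor Hobit (5.76 ± 0.37). Cd200r2, Xcr1, Cd200r1 and Gpr34 completed the 10, with log2 fold changes of 5.73, 5.53, 5.26 and 5.10, and Xcr1 is also a dendritic cell marker. Cxcr6 reached 1692 ± 381 CPM in ILC1 against 17.7 ± 0.390 CPM in cNK. Ccl1 stood at 33.0 ± 3.66 CPM in ILC1 but had only 0, 1 and 14 counts in cNK pools 1 to 3. The size of its change, and its rank as the largest, are therefore uncertain. Toward cNK, the largest differences were in the serine protease inhibitor Serpinb9b (-7.87 ± 0.46), the chymase Cma1 (-7.62 ± 0.92), the Ly49 receptors Klra4 (-7.52 ± 0.45) and Klra8 (-6.44 ± 0.40), and Cym (-6.65 ± 0.53). Mcam, Cmah, Eomes and Phactr3 were also among the 10, with -5.70, -5.55, -5.37 and -5.32. All 930 called genes had 3 libraries of one population above all 3 of the other, as had 24.1% of all tested genes, where chance gives 10%. The count of genes higher in ILC1 was 432 without ILC1 pool 2, 388 without cNK pool 1, 336 without cNK pool 2 and 214 without cNK pool 3. The count higher in cNK was 165 without ILC1 pool 2, 672 without ILC1 pool 3, 157 without cNK pool 2 and 93 without cNK pool 3, and the DESeq2 Wald test called 1153 and 693 genes.

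**Figure D1:**
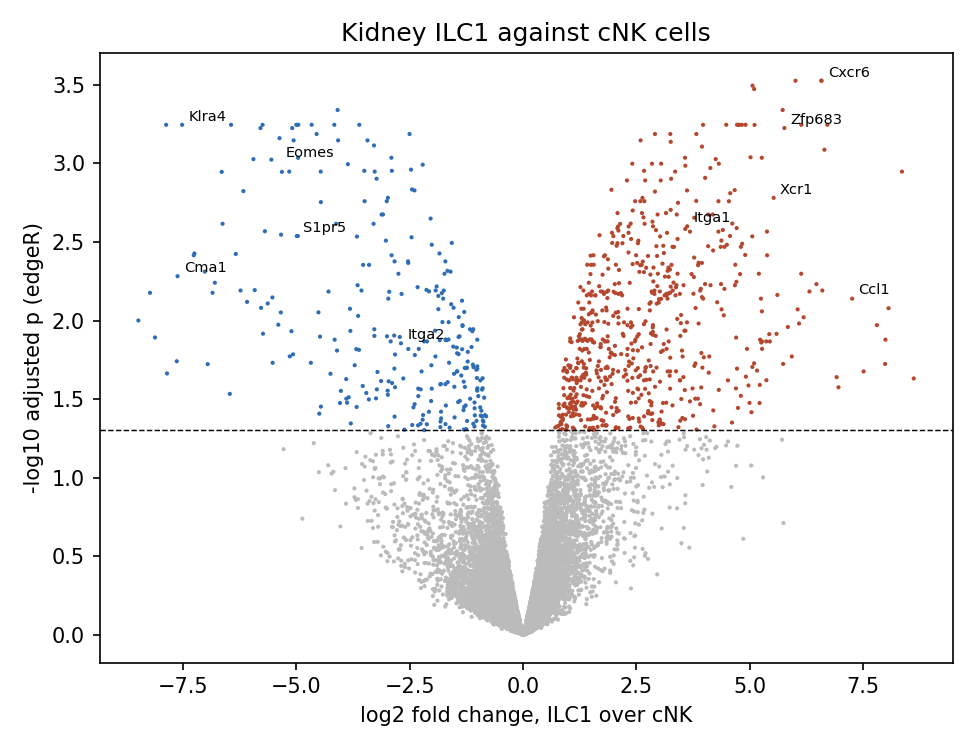
Each point is a tested gene, with the log2 fold change of ILC1 over cNK on the horizontal axis and -log10 of the edgeR adjusted p on the vertical axis, and the dashed line marks an adjusted p of 0.05. The 657 genes higher in ILC1 are red and the 273 genes higher in cNK are blue.

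Genes known to mark ILC1 in other tissues were mostly higher in the kidney ILC1. Of 24 tested, 19 were higher in ILC1 (21 adjusted over the list alone) and 0 were higher in cNK. Besides Cxcr6, Zfp683 and Cd200r1, they included Inpp4b, a phosphoinositide phosphatase (log2 fold change 4.83 ± 0.28), Tnfsf10, which encodes the death ligand TRAIL (4.25 ± 0.32), the interleukin 2 receptor chain Il2ra (3.82 ± 0.26) and the interleukin 7 receptor chain Il7r (3.26 ± 0.30). Itga1, on which the ILC1 were sorted, is another of these genes. Il7r stood at 127 ± 30.9 CPM in ILC1 and 13.3 ± 3.999 CPM in cNK. Camera called the list higher in ILC1 (adjusted p = 1.50e-64, and adjusted p = 0.0313 with an estimated correlation).

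Genes of mature cNK cells went the other way. Of 24 tested, 20 were higher in cNK (22 adjusted over the list alone) and 0 were higher in ILC1 (1 adjusted over the list alone). The genes higher in cNK include Itga2, on which the cNK were sorted. The T-box factor Eomes (chromosome 9, 118478212 to 118486132) averaged 357 ± 79.7 CPM in cNK and 8.62 ± 2.995 CPM in ILC1. Klrg1, an inhibitory receptor of mature NK cells, averaged 393 ± 43.5 and 16.7 ± 5.10 CPM, S1pr5, a receptor for exit from tissue, 344 ± 124 and 10.8 ± 6.21 CPM, and Itgam, which encodes CD11b, 87.4 ± 41.1 and 7.12 ± 4.56 CPM. The edgeR adjusted p of Itgam was 0.0154, and 0.0600 without cNK pool 3. Camera called the list higher in cNK (adjusted p = 2.05e-74, and adjusted p = 0.00920 with an estimated correlation).

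**Figure D2:**
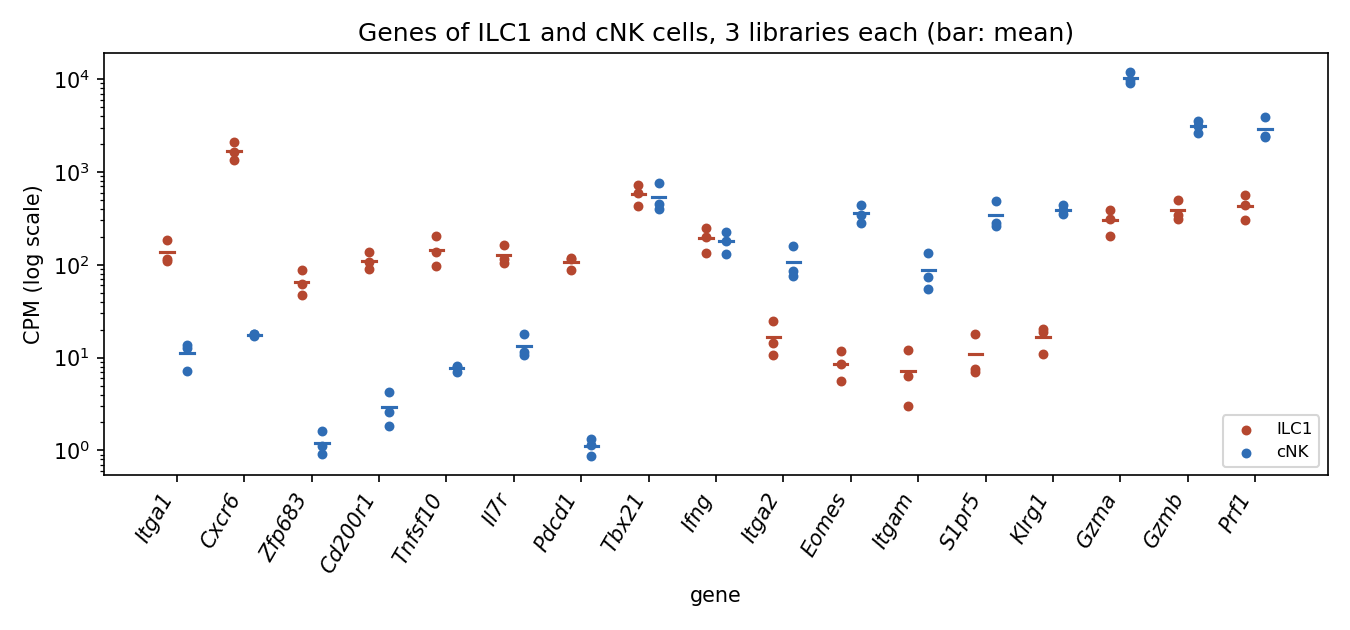
Points give TMM-scaled CPM of single libraries on a log axis for genes of both populations, with ILC1 in red, cNK in blue and the mean of 3 libraries as a bar. The ILC1 and cNK libraries overlap for Tbx21 and Ifng and are apart for each of the other genes shown.

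Transcription factors split between the populations. Of 36 tested, 8 were higher in ILC1 and 4 in cNK (12 and 6 adjusted over the list alone). Beside Zfp683, the nuclear receptor Rora (log2 fold change 2.59 ± 0.18), the aryl hydrocarbon receptor Ahr (2.52 ± 0.29) and Zbtb16, which encodes PLZF (1.53 ± 0.22), were higher in ILC1. Beside Eomes, Irf8 (-2.40 ± 0.21), Klf2, a regulator of lymphocyte trafficking (-1.84 ± 0.21), and Zeb2 (-2.84 ± 0.50) were higher in cNK. Tbx21, which encodes T-bet, stood at 582 ± 142 CPM in ILC1 and 536 ± 193 CPM in cNK (log2 fold change 0.12 ± 0.31), and Id2 (0.09 ± 0.31), Nfil3 (-0.40 ± 0.17), Gata3 (0.52 ± 0.21), Tcf7 (-0.21 ± 0.30) and Prdm1 (-1.17 ± 0.29) did not pass the edgeR test either. The edgeR adjusted p of Zeb2 was 0.0716 without ILC1 pool 1, 0.0525 without ILC1 pool 2, 0.0513 without cNK pool 1 and 0.0729 without cNK pool 3, and that of Zbtb16 was 0.0642 without cNK pool 3. Prdm1 was called lower in ILC1 by the DESeq2 Wald test (adjusted p = 0.00339) and by edgeR with upper-quartile factors (0.0344), pool number as a block (0.0118), the mitochondrial share as covariate (0.00737) or the kidney epithelial share as covariate (0.0280), and Nfil3 by the DESeq2 Wald test (0.0499). Without cNK pool 3, 5 of the factors were higher in ILC1. Camera did not call the list (adjusted p = 0.0593), but called it higher in ILC1 without ILC1 pool 3 (0.0122) and without cNK pool 3 (0.0367).

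Genes of the cytotoxic machinery were mostly higher in cNK where they passed the test. Of 23 tested, 8 were higher in cNK and 2 in ILC1 (9 and 2 adjusted over the list alone), and 5 were higher in cNK without cNK pool 3. Gzma, a granzyme, averaged 10278 ± 1432 CPM in cNK and 301 ± 90.9 CPM in ILC1, Gzmb 3092 ± 439 and 385 ± 105 CPM, and the pore-forming Prf1 2914 ± 869 and 433 ± 128 CPM. Gzmm was also higher in cNK (log2 fold change -3.61 ± 0.23). The 2 genes higher in ILC1 were Tnfsf10 and another granzyme, Gzmc, at 117 ± 46.3 against 4.61 ± 1.07 CPM. Camera called the list higher in cNK (adjusted p = 1.97e-06, but adjusted p = 0.103 with an estimated correlation).

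Cytokine and chemokine genes were higher in ILC1 for 11 of 23 tested and higher in cNK for 1 (11 and 3 adjusted over the list alone). Ltb, which encodes lymphotoxin beta (log2 fold change 2.87 ± 0.28), Tnf (3.19 ± 0.38), Tnfsf11, which encodes RANKL (3.17 ± 0.33), and Tnfsf14 (1.69 ± 0.17) were higher in ILC1, and the chemokine Ccl5 was higher in cNK (6935 ± 1183 against 1194 ± 365 CPM). Ifng, the interferon of type 1 lymphocytes, stood at 193 ± 57.5 CPM in ILC1 and 179 ± 45.7 CPM in cNK and did not pass (edgeR adjusted p = 0.862). Among 29 cytokine receptor genes, 7 were higher in ILC1 and 0 in cNK (13 and 0 adjusted over the list alone), including Il21r at 350.2 ± 78.02 against 60.5 ± 14.4 CPM. Csf2rb, also called, stood at 17.6, 7.72 and 20.02 CPM in ILC1 pools 1 to 3, where macrophage, monocyte and dendritic cell markers made up 0.618, 0.491 and 1.12% of counts, against at most 0.146% in cNK. The edgeR adjusted p of Csf2rb was 0.0589 without cNK pool 2 and 0.0540 without cNK pool 3. The count of cytokines and chemokines higher in ILC1 was 7 without ILC1 pool 2, 7 without cNK pool 1 and 5 without cNK pool 3, and that of the receptors was 4 without ILC1 pool 1, 4 without cNK pool 1, 3 without cNK pool 2 and 3 without cNK pool 3. Without ILC1 pool 3, 2 cytokines and chemokines and 1 receptor were higher in cNK. Camera called both lists higher in ILC1 (adjusted p = 1.13e-06 and 1.96e-06), with adjusted p = 0.128 and 0.212 with an estimated correlation.

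The Ly49 receptors, which bind MHC class I, were a feature of cNK. Of 12 tested, 8 were higher in cNK and 0 in ILC1 (9 and 1 adjusted over the list alone). Klra4 averaged 838 ± 76.3 CPM in cNK and 4.56 ± 2.18 CPM in ILC1, and Klra7 and Klra3 had log2 fold changes of -4.66 ± 0.27 and -3.27 ± 0.26. These genes are near-identical neighbours on chromosome 6, so that the values of single members are uncertain. Camera called the list higher in cNK (adjusted p = 3.50e-30, but adjusted p = 0.0559 with an estimated correlation). Of 30 other NK receptors and checkpoints, 9 were higher in ILC1 and 2 in cNK (13 and 6 adjusted over the list alone), with 4 in cNK without ILC1 pool 2 and 1 without cNK pool 3. Pdcd1 averaged 106 ± 16.4 CPM in ILC1 and 1.11 ± 0.227 CPM in cNK, the inhibitory receptor Ctla4 27.2 ± 4.73 and 0.907 ± 0.243 CPM, and the activating receptor Cd226 325 ± 63.5 and 45.2 ± 4.26 CPM. Camera called this list higher in ILC1 (adjusted p = 2.53e-04, but adjusted p = 0.466 with an estimated correlation).

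Genes of residency in tissue and of exit from it moved apart. Of 25 residency genes, 13 were higher in ILC1 and 0 in cNK (14 and 2 adjusted over the list alone), among them Cxcr6, Inpp4b and Zfp683, and also Itga1, on which the ILC1 were sorted, and 7 were higher in ILC1 without cNK pool 3. Of 14 genes of egress and recirculation, 7 were higher in cNK and 0 in ILC1 (8 and 0 adjusted over the list alone). The sphingosine phosphate receptor S1pr1 averaged 89.6 ± 15.8 CPM in cNK and 11.3 ± 3.12 CPM in ILC1, and Rasgrp2, an activator of Rap1, 50.6 ± 1.69 and 8.92 ± 0.532 CPM. Camera called the residency list higher in ILC1 (adjusted p = 2.34e-21, and adjusted p = 0.0169 with an estimated correlation) and the egress list higher in cNK (adjusted p = 3.02e-20, but adjusted p = 0.0614 with an estimated correlation). Of 32 genes of homing and adhesion, 9 were higher in ILC1, such as Cxcr3 (log2 fold change 2.91 ± 0.25), and 6 in cNK, such as Itga4 (-2.13 ± 0.27), with 11 and 8 adjusted over the list alone, and Itga1 and Itga2, the genes of the sort, are among the called members. Camera called that list higher in ILC1 (adjusted p = 0.00277, but adjusted p = 0.466 with an estimated correlation). Its camera adjusted p was 0.0724 without cNK pool 2, 0.230 with pool number as a block, 0.964 with the mitochondrial share as covariate and 0.187 with the kidney epithelial share as covariate.

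Camera called the lists of activation and of tissue handling higher in ILC1. Of 22 NF-kB target genes, 7 were higher in ILC1 and 0 in cNK (8 and 1 adjusted over the list alone), led by Ltb and Tnf (camera adjusted p = 5.89e-06, but adjusted p = 0.103 with an estimated correlation). Of 30 interferon-stimulated genes, 2 were higher in ILC1 and 0 in cNK (12 and 1 adjusted over the list alone), with a median log2 fold change of 0.73 (camera adjusted p = 8.33e-05, but adjusted p = 0.103 with an estimated correlation). Of 38 immediate early and dissociation genes, which rise when tissue is digested, 3 were higher in ILC1 and 0 in cNK, both over all genes and adjusted over the list alone (camera adjusted p = 0.00148, but adjusted p = 0.315 with an estimated correlation and 0.0572 without both ILC1 pool 3 and cNK pool 2). At an unadjusted edgeR p under 0.05 these were 12 and 2. DESeq2 called 8 NF-kB, 11 interferon-stimulated and 9 immediate early genes higher in ILC1, and 1 of each list higher in cNK. The NF-kB count was 4 without ILC1 pool 1, 3 without cNK pool 1, 3 without cNK pool 2 and 2 without cNK pool 3, the interferon count 1 without ILC1 pool 2, 5 without ILC1 pool 3, 1 without cNK pool 1 and 0 without cNK pool 3, and the immediate early count 1 without ILC1 pool 1 and 0 without cNK pool 2 or cNK pool 3. Of 28 macrophage, monocyte and dendritic cell markers, 11 were also called higher in ILC1 (camera adjusted p = 1.51e-14, but adjusted p = 0.212 with an estimated correlation). The list made up 0.618, 0.491 and 1.12% of counts in ILC1 pools 1 to 3, where Cd83, called in both the NF-kB and the immediate early list, stood at 111, 58.6 and 174 CPM. Cd83 was not called without ILC1 pool 1 (edgeR adjusted p = 0.0528), cNK pool 1 (0.0899), cNK pool 2 (0.0787) or cNK pool 3 (0.108), or with pool number as a block (0.0522). The 6 heat shock genes Hspa1a, Hspa1b, Hspa8, Dnajb1, Hsph1 and Hsp90aa1, grouped after their values were seen, made up 2.54 ± 0.318% of counts in ILC1 (SD, n = 3) and 1.56 ± 0.288% in cNK (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The correlation of this share with the mitochondrial share over the 6 libraries was -0.882 (Pearson r, exact permutation p = 0.0417, adjusted over 3 relations p = 0.0625). Spearman rho was -0.886 (exact permutation p = 0.0333, adjusted p = 0.05). The permutations exchanged libraries across both populations, so this correlation takes in the difference between ILC1 and cNK.

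Genes of growth and metabolism gave few calls. Of 22 glycolysis genes, 1 was higher in ILC1 and 2 in cNK (2 and 2 adjusted over the list alone), of 23 cholesterol synthesis genes 1 and 0 (1 and 0 adjusted over the list alone), and of 18 TGF-beta pathway genes 1 and 0 (3 and 0 adjusted over the list alone). Leaving out 1 library took the glycolysis count to 0 in ILC1 (cNK pool 1, 2 or 3) and to 1 (ILC1 pool 1, cNK pool 1 or 2) or 0 (ILC1 pool 2 or cNK pool 3) in cNK. The cholesterol count in ILC1 was 0 without any 1 library but ILC1 pool 2, and the TGF-beta count in ILC1 was 0 without ILC1 pool 2 or any 1 cNK pool, while 1 TGF-beta gene was higher in cNK without ILC1 pool 3. None of these 3 lists was called by camera (adjusted p = 0.447, 0.460 and 0.260). Of 36 cell cycle genes edgeR called 0, with 6 higher in cNK at an unadjusted p under 0.05, while DESeq2 called 3 and limma-voom 1 higher in cNK. Of 42 nuclear genes of oxidative phosphorylation and 87 cytosolic ribosomal protein genes edgeR called 0 and 0, with 4 and 3 higher in cNK at an unadjusted p under 0.05, where DESeq2 called 0 and 1 and limma-voom 0 and 0. Of 54 replication-dependent histone genes, 2 were higher in cNK (H2ac10 and H1f5, 0 adjusted over the list alone), with 14 at an unadjusted p under 0.05, where DESeq2 called 7 and limma-voom 1. H2ac10 was not called without any 1 of the 6 libraries (adjusted p = 0.0674 to 0.166), nor H1f5 without any 1 but ILC1 pool 3 (0.0575 to 0.143), nor either with the mitochondrial share (0.116 and 0.119) or the kidney epithelial share (0.108 and 0.0986) as covariate. Camera called these 4 lists higher in cNK (adjusted p = 0.00175, 4.15e-06, 2.29e-07 and 2.74e-06), with adjusted p = 0.466, 0.517, 0.549 and 0.466 with an estimated correlation. With the mitochondrial share as covariate the camera adjusted p was 0.475 for oxidative phosphorylation and 0.122 for ribosomal proteins, and that of cell cycle genes was 0.0721 without ILC1 pool 3. The median log2 fold changes were -0.37, -0.62, -0.57 and -0.79.

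Transcripts of other cell types differed between the populations and between libraries. Of 28 macrophage, monocyte and dendritic cell markers, 11 were higher in ILC1 and 0 in cNK (14 and 0 adjusted over the list alone). Xcr1, the receptor of cross-presenting dendritic cells, averaged 54.9 ± 16.1 CPM in ILC1 and 1.20 ± 0.578 CPM in cNK, Flt3 16.1 ± 3.60 and 0.389 ± 0.272 CPM, Mpeg1 42.7 ± 21.8 and 1.97 ± 0.642 CPM, and the MHC class II invariant chain Cd74 1875 ± 719.9 and 270.1 ± 100.4 CPM. The list made up 0.618, 0.491 and 1.12% of counts in ILC1 pools 1 to 3 and 0.140, 0.146 and 0.117% in cNK pools 1 to 3. The count higher in ILC1 was 7 without cNK pool 1 and 3 without cNK pool 3. Camera called the list higher in ILC1 (adjusted p = 1.51e-14, but adjusted p = 0.212 with an estimated correlation). Of 12 B cell markers, 3 were higher in ILC1 and 0 in cNK (4 and 0 adjusted over the list alone), with Ighm at 606 ± 97.9 against 176 ± 17.8 CPM, and the light chain gene Igkc stood at 116 CPM in ILC1 pool 3 and at no more than 2.09 CPM in the other 5 libraries (camera adjusted p = 0.0105, but adjusted p = 0.325 with an estimated correlation, 0.0640 without ILC1 pool 3 and 0.0534 without cNK pool 3). Ighm stood at 609, 703 and 507 CPM in ILC1 pools 1 to 3, so that it did not follow Igkc. The B cell count higher in ILC1 was 1 without any 1 of ILC1 pool 2 and cNK pools 1 to 3, where the other called members, Fcrla (edgeR adjusted p = 0.0579 to 0.123) and Ighd (0.0503 to 0.176), lost their calls, Ighd also without ILC1 pool 1 (0.0951) and with the mitochondrial (0.0543) or kidney epithelial share (0.0701) as covariate. Of 23 T cell markers, 7 were higher in ILC1 and 2 in cNK (10 and 2 adjusted over the list alone). The T cell receptor gamma constant gene Trgc4 (log2 fold change 4.41 ± 0.44), Bcl11b (3.16 ± 0.41) and Ubash3a (2.11 ± 0.25) were higher in ILC1, and Cd247, the CD3 zeta chain also used by NK receptors (-2.45 ± 0.21), and Trdc (-2.04 ± 0.20) were higher in cNK. Camera called the T cell list higher in ILC1 (adjusted p = 2.77e-04, but adjusted p = 0.103 with an estimated correlation), and the edgeR adjusted p of Bcl11b was 0.0540 without cNK pool 3.

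Some markers of other innate lymphoid cells were higher in ILC1. Of 11 ILC2 markers, 3 were higher in ILC1 (Arg1, Il2ra and Areg) and 1 in cNK (Klrg1), and of 11 ILC3 markers 3 were higher in ILC1 (among them Ltb and Lta) and 0 in cNK, with 3 and 1 and with 8 and 0 adjusted over the list alone. Arginase 1 (Arg1) averaged 32.8 ± 3.40 CPM in ILC1 and 0.982 ± 0.106 CPM in cNK. Il2ra and Ltb also stood in the ILC1 list and Klrg1 in the list of mature cNK genes. Camera called both lists higher in ILC1 (adjusted p = 0.00382 and 5.77e-06, but adjusted p = 0.103 and 0.103 with an estimated correlation). Of 8 neutrophil, mast cell and basophil markers, 1 was higher in ILC1 (Mmp9) and 0 in cNK, over all genes, with 1 and 1 adjusted over the list alone (camera adjusted p = 0.460, toward ILC1 while the median log2 fold change was -0.89). The edgeR adjusted p of Areg was 0.0716 without cNK pool 3, and that of Lta was 0.0546 without ILC1 pool 2 and 0.0831 without cNK pool 3. The ILC3 count was 1 without cNK pool 3, and 3 neutrophil, mast cell and basophil markers were higher in cNK without ILC1 pool 3.

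Kidney epithelial transcripts varied within both populations. EdgeR called 0 of 26 epithelial markers, with 7 higher in cNK at an unadjusted p under 0.05, where DESeq2 called 5 and limma-voom 0 (median log2 fold change -1.50). On lists chosen after seeing the data, it called 0 of 11 proximal tubule genes, with a median log2 fold change of -2.12 (quartiles -2.99 and -1.70). It also called 0 of 13 genes of the loop, distal tubule and collecting duct (median -0.80). The lack of calls thus does not show that the cNK libraries hold no more tubule RNA. Gpx3, a product of the proximal tubule, averaged 525 ± 95.5 CPM in ILC1 and 1905 ± 1332 CPM in cNK, and Umod, the product of the thick ascending limb, 604 ± 642 and 743 ± 329 CPM. Gpx3 was called higher in cNK by DESeq2 (adjusted p = 0.0182) and without cNK pool 1 (0.0112), and edgeR called 4 epithelial markers without ILC1 pool 3 and 8 without cNK pool 1. The list made up 0.149, 0.104 and 0.496% of counts in ILC1 pools 1 to 3 and 0.197, 0.782 and 0.605% in cNK pools 1 to 3. Mitochondrially encoded genes took 1.38, 2.25 and 6.53% of counts in ILC1 and 3.15, 12.7 and 10.3% in cNK (exact permutation p = 0.2, two-sided). Their nuclear copies on chromosome 1 took a further 0.850, 1.43 and 3.84% in ILC1 and 1.96, 8.05 and 5.98% in cNK. Counts of the copy Gm28437 were 1.04 times those of mt-Co3 in each of the 6 libraries, so that it is uncertain whether such reads were counted once. Of 19 mitochondrial genes edgeR called 0, with 5 higher in cNK at an unadjusted p under 0.05, DESeq2 and limma-voom called 0 and 0, and edgeR called 6 without ILC1 pool 3. Camera called both lists higher in cNK (adjusted p = 3.68e-05 and 6.09e-06, but adjusted p = 0.466 and 0.466 with an estimated correlation, and 0.739 for the epithelial list with the mitochondrial share as covariate). EdgeR, DESeq2 and limma-voom each called 0 of 17 endothelial and stromal markers and 0 of 9 erythroid and platelet markers, with 0 and 1 at an unadjusted p under 0.05 toward cNK (camera adjusted p = 0.134 and 0.210). Car2, of the erythroid and platelet list, was called higher in cNK by edgeR with pool number as a block (log2 fold change -0.87, adjusted p = 0.0434). Without ILC1 pool 3 edgeR called 2 endothelial and stromal and 1 erythroid or platelet marker higher in cNK, and camera called the endothelial and stromal list higher in cNK (adjusted p = 2.60e-04) and, without cNK pool 3, the erythroid and platelet list (0.0407). Of 4 sex-linked genes tested edgeR called 0, with 2 higher in ILC1 at an unadjusted p under 0.05 and adjusted over the list alone, where DESeq2 called 1 and limma-voom 0 (camera adjusted p = 0.210), and the Y-linked Ddx3y stood at 75.6 ± 15.7 CPM in ILC1 and 59.9 ± 14.3 CPM in cNK.

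**Figure D3:**
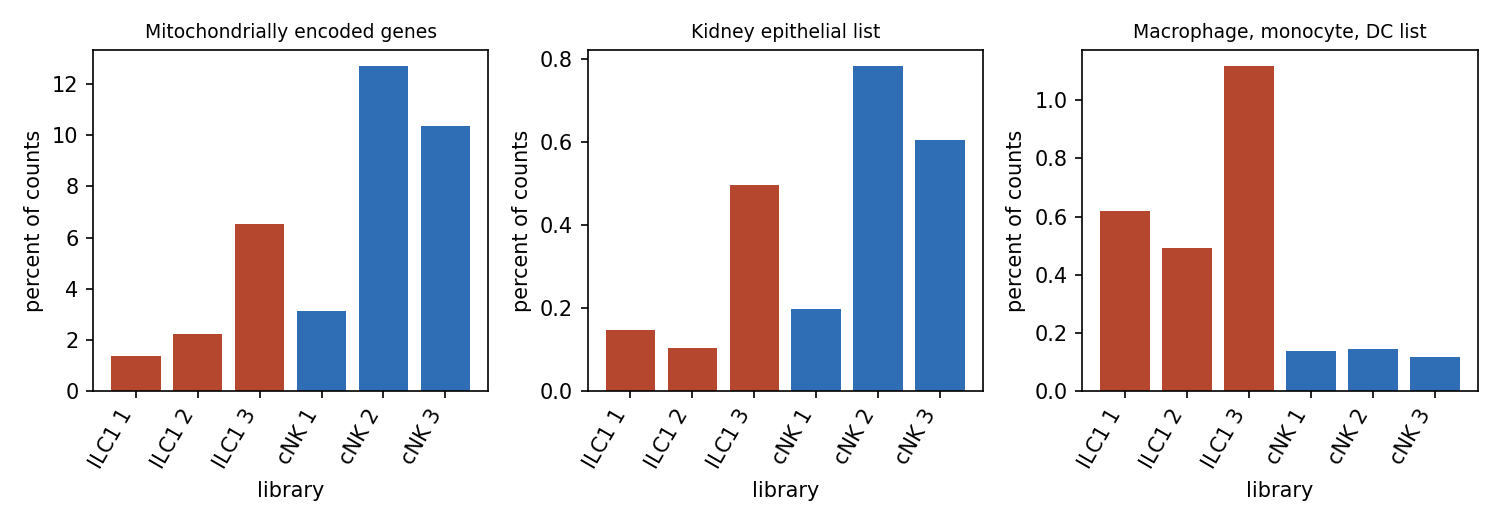
Bars give the percent of each library's counts in mitochondrially encoded genes, kidney epithelial markers and macrophage, monocyte and dendritic cell markers, with ILC1 in red and cNK in blue. The mitochondrial share runs from 1.38% to 12.7%, and the macrophage, monocyte and dendritic cell share is above 0.146% only in the 3 ILC1 libraries.

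The authors' deposited lists held the 2000 genes with the highest mean count in each population, in the order of the deposited mean columns. Of these genes, 1721 (86.05%) were in both lists and 279 in each list alone. Of the genes in the ILC1 list alone, 93 were called higher in ILC1 and 0 higher in cNK. Of those in the cNK list alone, 39 were called higher in cNK and 0 higher in ILC1. The lists rank the mean counts of these same libraries, so that calls against the direction of a list could hardly occur. Among the shared genes, 24 were called higher in ILC1 and 32 in cNK. In the cNK list, 6 of the 10 first entries were mitochondrial genes or their nuclear copies on chromosome 1, such as mt-Co3 and Gm28437. Gm28437 lies at chromosome 1, 24613189 to 24613971 and is annotated as an unprocessed pseudogene.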

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

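The DESeq2 size factors, upper-quartile factors, limma-voom, the fits with no filter and with the stricter filter, and the limit of 1 on the absolute log2 fold change kept both counts of called genes within 1.5 times. Other settings moved them: the DESeq2 Wald test gave 1153 genes higher in ILC1 and 693 higher in cNK, and an adjusted p under 0.01 gave 263 and 108. Leaving out 1 library gave between 214 and 695 genes higher in ILC1 and between 93 and 672 higher in cNK, and without ILC1 pool 3 and cNK pool 2, chosen after seeing the data, 481 and 431. The cause was not tested. With pool number as a block, 1107 genes were higher in ILC1 and 675 in cNK. The labels number the pools of both populations 1 to 3 but do not say that same-numbered pools share mice. The main test was for that reason set as unpaired before the data were examined. Same-numbered pools deviated together from their population means for pool 1 (correlation 0.53) but not for pool 2 (-0.13) or pool 3 (0.06). ILC1 pool 3 went best with cNK pool 2 (0.59). Deviations from means of 3 libraries, which also differ in mitochondrial share, cannot decide whether the pools are paired. No called gene changed sign in any of the 17 refits that tested it. The populations did not overlap for any of the 930 called genes. Refits that left out libraries could therefore hardly reverse a sign, and are no test of it. Of 128 named genes 85 were called, 59 of them in every refit, and 31 of the others were called in none.

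Of 33 lists 24 were called by camera, fry called 16, and 3 held with an estimated correlation, those of ILC1, mature cNK and residency genes. Lists share members and are not separate results. Cxcr6, Inpp4b and Zfp683 are in both the ILC1 and the residency list, and Klra4, Klra7 and Klra8 in both the mature cNK and the Ly49 list. Leaving out 1 library gave between 23 and 25 lists. There were 22 with the kidney epithelial share as covariate or without both ILC1 pool 3 and cNK pool 2, and 19 with the mitochondrial share as covariate, which ended the calls of the lists of homing and adhesion, oxidative phosphorylation, ribosomal proteins and kidney epithelium. The loss of the mitochondrial list under its own share, and of the epithelial list under its own, was fixed by the covariate and is no test. Within lists, leaving out 1 library moved a count of calls by over 1.5 times in 22 of 33 lists, and in 17 without cNK pool 3. The authors' top lists shared 86.05% of genes, 84.1% over the first 1000 and 80.8% over the first 500, and 85.8% or 84.9% when ranked by mean or median CPM. Having 3 pools per population limits what can be seen. In simulated data 4 of 50 genes changed 2-fold were recovered, but at a stricter adjusted threshold than in the data. In the data, 621 of the 657 genes called higher in ILC1 and 257 of the 273 higher in cNK changed over 2-fold.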

Other observations

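Families of genes that share a symbol stem were searched after the data were seen, with Fisher's exact test over 256 families of at least 8 tested members, and 12 of 512 tests passed an adjusted p of 0.05. Besides the Ly49 (Klra) genes, 4 of 14 Klf genes were higher in cNK (Klf2, Klf3, Klf7 and Klf12, adjusted p = 0.00489). So were 5 of 37 Cyp genes (Cyp17a1, Cyp2a5, Cyp4a10, Cyp4a14 and Cyp4a31, adjusted p = 0.0159). The same held for 3 of 8 Rap genes (Rap1gap2, Rap2a and Rap2b, adjusted p = 0.0129). Whether kidney epithelial RNA was the source of the Cyp calls was not tested. Among families higher in ILC1 were 5 of 9 Toll-like receptors (Tlr3, Tlr7, Tlr11, Tlr12 and Tlr13, adjusted p = 0.00124), 6 of 17 Ifi genes (adjusted p = 0.00319), 4 of 9 Tnfsf genes (Tnfsf8, Tnfsf10, Tnfsf11 and Tnfsf14, adjusted p = 0.0135, while Tnfsf4 and Tnfsf12 were called higher in cNK) and 5 of 8 tested immunoglobulin heavy chain variable genes (adjusted p = 7.12e-04). Tlr3 and Tlr13 are also on the lists of dendritic cell and monocyte genes used below, whose first list made up 0.491 to 1.12% of counts in ILC1 and at most 0.146% in cNK. Beside the immunoglobulin genes, 3 of 12 B cell markers were called higher in ILC1, and 1 without ILC1 pool 2 or any 1 cNK pool. Whether B cells were the source of these transcripts was not tested. Genes of a family can share reads and are not independent.

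Of the tests of explanations given here, 2 were set before their results were seen (the other splits of the libraries, and the second lists for dendritic cells and monocytes), and the others were chosen after. The second lists were themselves chosen after the data were seen. The real split of the 6 libraries gave 930 called genes with edgeR, and the highest of the 9 other splits gave 0, so that 1 of 10 splits gave as many, too few splits for a share under 0.05. At an unadjusted p under 0.05 the real split gave 2903 genes, and the split of ILC1 pools 1 and 2 with cNK pool 1 against the rest gave 3561. That split parts the 3 libraries of lowest mitochondrial share from the 3 of highest, and points to a structure of the samples other than population.

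Of 28 dendritic cell, macrophage and monocyte markers, 11 were called higher in ILC1 (7 without cNK pool 1, 3 without cNK pool 3, and list adjusted p = 0.212 with an estimated correlation), although the gate on NK1.1 and NKp46 would remove such cells. Of 32 tested genes on 2 further lists, none of them on the first list, 53.1% were called higher in ILC1. This is just above 50%, the bound set before this result as a sign of dendritic cells and monocytes within the ILC1 gate. The 2 lists were themselves chosen after the data were seen, and were counted in the same 6 libraries. They are therefore no independent test, and the share was not checked with single libraries left out. Dendritic cells and monocytes within the ILC1 gate may be the source of these transcripts. Of the 32 genes, P2ry14 was called higher in cNK (log2 fold change -1.71), and 11 averaged at least 10 CPM in cNK and are not specific to those cells, while Lyz2 stood at 448, 255 and 1618 CPM in the ILC1 pools and at most 71.4 CPM in cNK. Free RNA of the digest stays open: the smallest ratio of the first list to kidney epithelial transcripts in ILC1 was 3.18 times the largest in cNK, but the ratio of proximal to distal tubule transcripts varied 9.97-fold over the libraries, so that such RNA need not keep 1 profile. Expression by ILC1 themselves, a biological difference between the populations, stays open and was not tested.

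The mitochondrial share ranged from 1.38 to 12.7%. It rose with the kidney epithelial share over the 6 libraries (Pearson r = 0.983, exact permutation p = 0.00278, adjusted over 3 relations p = 0.00833; Spearman rho = 0.943, exact permutation p = 0.0167, adjusted p = 0.05, at the threshold), the other relations being with the heat shock share (r = -0.882, adjusted p = 0.0625) and the total count (r = -0.00786, adjusted p = 0.990). These permutations exchanged libraries across both populations, so the relations take in any difference between ILC1 and cNK. The epithelial r was 0.962 without cNK pools 2 and 3. That value rests on ILC1 pool 3, with 0.496% epithelial and 6.53% mitochondrial counts, where the other libraries left had at most 0.197% and 3.15%. Carried-over epithelial RNA may account for the mitochondrial share, but leaving out these pools adds little for it. Within populations, genes with a longer total exonic sequence, merged over their annotated transcripts, fell as the share rose (Spearman rho = -0.271 across genes, which are not independent replicates). Loss of long transcripts is thus also possible, but the length of the transcripts expressed was not measured. A difference between ILC1 and cNK stays open (exact permutation p = 0.2, two-sided). Adding the share as a covariate gave 706 genes higher in ILC1 and 400 in cNK.

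Of 23 T cell markers, 7 were called higher in ILC1 (median log2 fold change of the list 1.09), from a gate that excluded CD3. Against T cells in the gate as the main source of Cd3g, Trgc4, Bcl11b, Ubash3a and Cd28, the mean of Cd3d and Cd3e, which T cells carry, was at most 23.7% of the excess of any of these genes over cNK in the same ILC1 library (that of Bcl11b in ILC1 pool 3, just under a bound of 25% chosen after the values were seen, and at most 15.4% for the other 4). These 5 genes were also parted from Camk4 and Trgc1 after the values were seen, so that passing the bound is in itself no test. Against gamma-delta T cells as the main source of Trgc4, Trdc was at most 4.01% of its excess, and lower in ILC1 than in cNK (log2 fold change -2.04). For Trgc1, with a mean excess of 3.82 CPM, the mean of Cd3d and Cd3e was 58.3 to 175% of the excess. For Camk4, with a mean excess of 17.6 CPM, that level was 16.2 to 49.0%. These percentages set a level against an excess. The mean of Cd3d and Cd3e itself showed no excess in ILC1, at 4.52 ± 2.13 CPM against 5.85 ± 1.999 CPM in cNK (mean ± SD). Cd3e leaned toward ILC1 (log2 fold change 1.09) and Cd3d toward cNK (-0.71), and neither passed the edgeR test. The percentages thus give T cells no backing as the source of Trgc1 and Camk4, but the spread is too wide to exclude them. Transcription of the 5 genes in ILC1 themselves is a hypothesis that was not tested.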
